A study of Mus musculus with 2 samples.

How the data were processed

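The series holds 2 samples of total RNA from mouse 3T3 fibroblasts, 1 kept in suspension and 1 plated on fibronectin, each hybridised as biotin-labelled target to 1 Affymetrix MG_U74Av2 array. RNA was prepared with RNeasy columns, per the labels' protocols, and had a concentration of 2.5 µg/µl in both samples. The groups were taken from the sample titles. The series text mentions 2 replicates beside the 2 samples, whereas the labels give 1 sample per group, and no second array per group was analysed here. Whether the cells were of 1 culture and how long they were held in suspension is not given in the sources used here.

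The deposited values are intensities, 1 signal per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5 and its scaling target are not given in the sources used here, and its detection calls were not used here. The 2% trimmed means of the deposited intensities were 1489 and 1486, which is what scaling each array as a whole to 1 target gives, while the medians were 785 in suspension and 678 on fibronectin. The other deposited files, 1 per array, hold text settings of the instruments and no expression values. Of 32 settings filled in for both arrays, 4 differed: the chip lot, the operator, the fluidics module and the scan day. As each group lies in 1 array, these settings and the group cannot be told apart.

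Each array was divided by its 2% trimmed mean over the 12422 probe sets that are not controls and multiplied by the mean of both trimmed means, which gave factors of 0.999 and 1.00. A common floor was set at the mean of both arrays' 40th percentiles, a signal of 490, after scaling and before log2 was taken. The ratio of a probe set was the difference of the floored log2 signals, fibronectin minus suspension. A ratio with 1 array below the floor is a bound and is written as at least N-fold. A gene counted as measured if at least 1 array reached the floor. At or above the floor were 7629 probe sets in suspension and 7261 on fibronectin.

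Probe sets were named from the platform annotation. Of all 12488 probe sets, 10855 had 1 gene symbol, 396 had several and were not named, and 1237 were not listed and are unnamed here. By gene ID, 10839 probe sets matched the RefSeq gene table of the assembly GRCm38.p6, used for names and gene lengths, and 0 symbols were changed by it. For a gene with several probe sets, the one with the highest mean log2 signal was used. Where the text names a gene with another measured probe set of the opposite sign, that ratio, or its bound, is given. Probe sets that can detect related sequences, such as those of Actb, Itgb1, Ighv5-12 and Snrp1c-ps2, may include signal of such relatives. No coordinates are given, since the sources used here name no genome build.

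With 1 array per group there was no test between groups. Genes were counted by the size of their ratio, at 2-fold, 1.5-fold and 3-fold. For each of 30 gene lists written before the data were examined, the median ratio of its measured members was placed among the medians of 10000 random lists of the same size, drawn from measured genes matched on mean log2 signal in 20 bins. A list is said to stand apart when its median lies outside the central 95% of them, which describes these 2 arrays and is not a p-value. If genes varied independently, 1.5 of the 30 lists would stand apart by chance, and 7 did. Members of a list can vary together and lists share genes, so the true number to set beside these 7 is not known. The lists were immediate early genes, ERK feedback genes, MAPK components, integrins and focal adhesion proteins, SRF and actin genes, extracellular matrix, matrix proteases and inhibitors, NF-kB and inflammation, interferon response, heat shock, ATF4 and endoplasmic reticulum stress, p53 targets, hypoxia and glycolysis, cholesterol synthesis, G1 cyclins and growth regulators, S phase, mitosis, TGF-beta and Smad targets, growth factors and cytokines, ribosomal proteins, oxidative phosphorylation and histones. The other 7 held markers of fibroblasts, muscle, macrophages and blood cells, epithelium, endothelium, adipocytes and neural cells. Some genes belong to more than 1 list.

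The genes named were fixed by a rule written before the data were examined. It takes the 10 highest and the 10 lowest genes without another measured probe set of the opposite sign beyond 0.3 on the log2 scale, which passed over 1 gene among the lowest. It also takes up to 6 members with the largest absolute ratio from each list that stood apart and up to 3 from every other list. A set of always-reported genes was added: Fos, Egr1, Jun, Junb, Myc, Dusp1, Ccn1, Ccn2, Map2k1, Fn1, Itgb1, Itga5, Actb and Gapdh, of which Gapdh was read from its control probe sets, while Mapk3 was not analysed here. A few genes and 1 of the 30 lists are not reported here.

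The error of a ratio was estimated from genes with more than 1 measured probe set, as the SD of the difference between the log2 ratios of the brightest 2, divided by the square root of 2. It covers differences between probe sets within these arrays and not those between cultures, and the number of arrays limits the precision of every value. The procedure was checked on simulated arrays built from the real mean signals and this spread, with 200 genes changed by known amounts, 50 for each size and direction. Of genes made 4-fold higher, 88.0% came out at least 2-fold higher, and of genes made 4-fold lower, 80.9% came out at least 2-fold lower. For genes made 2-fold higher or lower the shares were 44.4% and 31.9%. Of 100 simulated lists of 30 genes shifted by 0.5 on the log2 scale, 87 stood apart above, with a mean recovered median of 0.46, and 4 of 100 unshifted lists stood apart. The simulated genes varied independently, so this does not give the rate for lists whose members vary together. The spread came from floored ratios and the simulated signals were floored again, so noise of low signals may be understated there.

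The alternatives written before the data were examined were the values as deposited, median scaling, quantile normalization, a loess fit of the ratio on signal with a span of 0.3, floors at the 20th and 60th percentiles, no floor, an offset in place of the floor, the mean of all measured probe sets of a gene, plain probe sets alone, a 3-fold threshold and a count of single probe sets. The 34 negative control probe sets comprise 15 for antisense strands, 15 for Bacillus genes and 4 for yeast genes, and the text measures background against all 34. A floor at the mean of both arrays' 95th percentiles of these 34 probe sets, a signal of 1638, was added after seeing the data. So was a scaling in which the median log2 ratio of the 9 hybridisation spikes is 0. Computations were run in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.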

Results

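Gene expression was measured in 3T3 cells, an immortalised line of mouse embryo fibroblasts that normally grows attached to a surface, in 2 conditions with 1 Affymetrix MG_U74Av2 array each. In the suspension group the cells were held unattached in serum-free medium. In the fibronectin group they were plated for 30 min on 10 µg/ml fibronectin, an adhesive glycoprotein of the extracellular matrix that cells bind through integrins. According to the labels, the suspension sample serves to find genes that fibronectin induces, and the plated sample was made to look at how MAPK signalling genes are expressed. Of 8251 genes named by at least 1 probe set, 6385 were measured, with a signal at or above a common floor of 490 in at least 1 array. Their log2 signals correlated between the arrays with r = 0.88 across genes, which are not independent replicates. As each group had 1 array, no difference below has a replicate check or a p-value, and "higher" and "lower" describe these 2 arrays.

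The gene with the highest ratio on fibronectin was Notch1, the receptor of the Notch pathway, at least 13.6-fold above suspension in its brightest probe set, with a log2 ratio of 0.67 in the other. With the floor at the 20th percentile or with no floor the other probe set was read, and Notch1 was neither first nor 2-fold higher. It was followed by Slc20a1, a sodium-dependent phosphate transporter, at least 11.5-fold higher, and by Itga5, the alpha subunit of the main fibronectin receptor, at least 9.40-fold higher with a signal of 4604 on fibronectin. Mthfd2, a mitochondrial enzyme of folate metabolism, was at least 6.52-fold higher and the collagen receptor Mrc2 at least 6.21-fold. The ephrin ligand Efna1 was at least 5.73-fold higher and the angiogenic growth factor Vegfa at least 5.62-fold. The signals of Mthfd2, Mrc2, Efna1 and Vegfa on fibronectin were 3192, 3043, 2806 and 2753, and the highest negative control there, an antisense probe set, had 2527. None of them kept a 2-fold difference under every alternative. As the floor lies within the range of the negative controls, such bounds hold against the floor and not against background. Among the 10 highest genes, those measured above the floor in both arrays were the cytochrome P450 gene Cyp1b1 (6.33-fold), Tmem41b (log2 ratio 2.58) and the proton pump subunit Tcirg1 (5.87-fold). Their suspension signals, 1106, 620 and 684, lay below the 95th percentile of negative controls there, 1403, so the size of these folds is uncertain. They stayed at least 2-fold higher under every alternative. The 10 lowest genes on fibronectin included several that are typical of other tissues. Clps, the colipase of the pancreas, was at least 5.59-fold lower, the immunoglobulin segment Ighv5-12 at least 5.31-fold, the pituitary hormone gene Prl at least 5.11-fold and the leukocyte ligand Selplg at least 5.10-fold. The others were the clock gene Per3 (5.17-fold lower), Tenm4 (at least 5.13-fold), Hmgn5 (at least 5.12-fold), Sult4a1 (at least 5.02-fold), the keratin gene Krt17 (4.97-fold) and the pseudogene Snrp1c-ps2 (4.77-fold). Another probe set of Tenm4 was at least 1.04-fold higher on fibronectin, and one of Krt17 at least 1.03-fold higher, both near the floor. The signals of Per3 and Krt17 on fibronectin, 500 and 492, lay near the floor and among the negative controls, and with the floor at the level of these controls their log2 ratios were -0.66 and -0.58.

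In all, 370 genes were at least 2-fold higher on fibronectin and 592 at least 2-fold lower, so that 38.5% of these genes were higher. Of the higher genes 146, and of the lower genes 281, had the other array below the floor. Among genes above the floor in both arrays, 224 were higher and 311 lower. By tertile of signal, 138 were higher and 262 lower in the lowest, 144 and 284 in the middle and 88 and 46 in the highest. Median scaling, which raised the median log2 ratio of all measured genes by 0.19, gave 596 higher and 405 lower genes. Quantile normalization gave 468 and 450, and a loess fit gave 467 and 441. With the arrays scaled to 9 hybridisation spikes, control transcripts added before hybridisation, 135 were higher and 1396 lower. The median log2 ratio of all measured genes was then -0.51, and of the lists only matrix proteases and inhibitors had a median above 0. In simulated arrays with no true change and the spread seen between probe sets of 1 gene, 335 of 5986 measured genes came out at least 2-fold higher and 315 lower. That spread came from floored ratios, and the simulated signals were floored again. Noise of low signals, and with it these simulated counts, may thus be understated.

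The immediate early genes, the first genes that growth factor and adhesion signals switch on, showed no common direction. Of 50 measured members, 12 were at least 1.5-fold higher on fibronectin and 7 at least 1.5-fold lower. The largest ratios belonged to Tiparp, at least 4.10-fold higher, the AP-1 subunit Fosl1, at least 3.95-fold higher, and the urokinase receptor gene Plaur, at least 3.77-fold higher. Their signals on fibronectin were 2010, 1934 and 1849, below the highest negative control signal there, 2527, which was that of an antisense probe set. The classical members were already bright in suspension. Egr1 had a signal of 24681 in suspension and 26466 on fibronectin. Its second probe set had a log2 ratio of -0.35, with signals of 823 and 647, within the range of the negative controls. Of the 50 genes, 19 lay among the top 10% of signals in both arrays, 14 of them with both signals within 1.5-fold of each other. Fos had a signal of 24717 in suspension against 12413 on fibronectin (log2 ratio -0.99). Its second probe set was at least 1.28-fold higher on fibronectin, but with signals of 199 and 627, within the range of the negative controls. Junb was 2.05-fold lower in its brightest probe set and 1.46-fold lower in the other. The matricellular gene Ccn2 was 2.85-fold lower and the differentiation inhibitor Id1 2.54-fold lower. Jun, Dusp1 and Ccn1 had log2 ratios of -0.56, -0.32 and -0.04, and Myc had 0.51. The median log2 ratio of the list was 0.05, at percentile 69.8 of 10000 random lists matched on signal. It was -0.03 after quantile normalization and -0.01 after loess, so its sign was not settled, 0.25 under median scaling and -0.42 with scaling to the spikes.

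**Figure D1:**
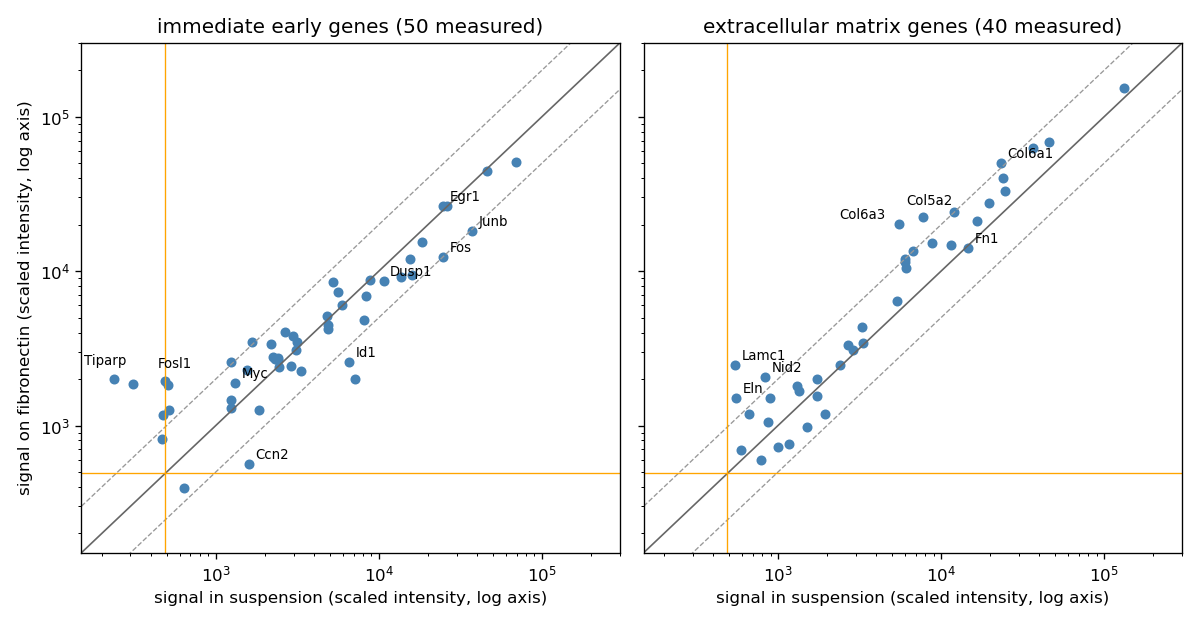
Signal of each measured immediate early gene (left, 50 genes) and extracellular matrix gene (right, 40 genes) in suspension (x axis) and on fibronectin (y axis), as scaled intensity on log axes, with 1 array per group. The solid line marks equal signals, the dashed lines 2-fold differences and the orange lines the floor of 490; immediate early genes lie on both sides of the solid line, and 33 of the 40 matrix genes lie above it.

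The components of the MAPK pathways, which the labels name as the aim, did not move in 1 direction either. Of 45 measured members, 8 were at least 1.5-fold higher on fibronectin and 8 at least 1.5-fold lower, and 4 each passed 2-fold. The kinase genes Mapk9 (JNK2) and Map2k4 (MKK4, which activates JNK) were 2.77-fold and 2.70-fold lower. Their signals on fibronectin, 509 and 827, lay below the 95th percentile of negative controls there, 1873. Mknk1, a kinase that ERK and p38 activate, was 2.64-fold higher, with signals of 699 in suspension and 1850 on fibronectin. These lay below the arrays' 95th percentiles of negative controls, 1403 and 1873, so these folds rest on signals near background. Map2k1 (MEK1) had a log2 ratio of -0.58 and was at least 1.47-fold lower in its second probe set. The median of the list was 0.07, at percentile 92.2. It was -0.15 with the floor at the 20th percentile of signals, -0.045 at the 60th and -0.35 with scaling to the spikes, so its sign was not settled. Mapk3 was not analysed here. Of 10 measured ERK feedback genes, 8 were below a ratio of 0, with a list median of -0.31 at percentile 9.50. Under median scaling 6 were below 0 and 4 above, with a median of -0.10. The phosphatase gene Dusp6 was 3.29-fold higher in its brightest probe set and at least 1.05-fold lower in another. Etv4 was 2.41-fold lower and Spry4 1.67-fold lower, and the other probe set of Etv4 was at least 1.33-fold higher.

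Genes of the extracellular matrix were higher on fibronectin as a group, relative to genes of similar signal. Of 40 measured members, 33 had a ratio above 0, 17 were at least 1.5-fold higher and 3 at least 1.5-fold lower, and 6 were at least 2-fold higher against 0 lower. The collagen genes Col6a3, Col5a2 and Col6a1 were 3.64-fold, 2.91-fold and 2.15-fold higher, with signals on fibronectin of 20117, 22530 and 49891. A second probe set of Col6a1 was 1.46-fold higher. Elastin (Eln) was 2.74-fold higher and the basement membrane gene Nid2 2.48-fold, from signals of 555 and 834 in suspension, within the range of the negative controls. With the floor at the level of these controls Eln was not measured and Nid2 had a log2 ratio of 0.33. The laminin chain gene Lamc1 was 4.58-fold higher in 1 probe set and had a log2 ratio of -0.31 in the other. Fn1, the gene of fibronectin itself, had signals of 14584 and 14072. The median log2 ratio of the list was 0.42, at percentile 99.97 of matched random lists, and -0.06 at percentile 99.96 with scaling to the hybridisation spikes. Proteases of the matrix and their inhibitors were higher too, with 10 of 19 measured members at least 1.5-fold higher and 1 lower, and a median of 0.62 at percentile 99.99, or 0.20 with that scaling. The collagenase Mmp13 was 3.01-fold higher, the inhibitor Timp2 3.29-fold, the lysosomal protease Ctsl 2.73-fold, the plasminogen activator Plat 1.95-fold and the membrane protease Adam10 1.84-fold. Mmp9 was 3.72-fold higher in 1 probe set and had a log2 ratio of -0.48 in the other. Both lists stayed outside the central 95% of matched random lists under all 12 alternatives run.

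Genes that respond to ATF4 and to stress of the endoplasmic reticulum formed another group that stood higher on fibronectin, with a more mixed make-up. Of 35 measured members, 20 had a ratio above 0 and 15 below, 10 were at least 1.5-fold higher and 5 lower, and 8 were at least 2-fold higher and 2 lower, with a median of 0.38 and percentile 99.94. With scaling to the spikes the median was -0.09. Beside Mthfd2 and Vegfa, the largest ratios were those of the protein disulfide isomerases Pdia6 (4.34-fold) and Pdia3 (3.99-fold) and of the chaperone cofactor Dnajb9 (3.39-fold). The other probe sets of Pdia6 were 2.48-fold and at least 2.66-fold higher, and the second of Dnajb9 was at least 3.29-fold higher. The lectin chaperone Canx went the other way, 2.88-fold lower in 1 probe set, with 0.01 in the other. Cholesterol synthesis genes had a median of 0.28 at percentile 97.62, with 9 of 19 measured members at least 1.5-fold higher and 1 lower. Sqle, the squalene epoxidase, was 3.21-fold higher, the squalene synthase gene Fdft1 3.14-fold, the desaturase gene Scd2 2.36-fold, Msmo1 1.79-fold and Nsdhl 1.71-fold. A second probe set of Scd2 was 1.42-fold higher. The suspension signal of Fdft1, 671, lay below the 95th percentile of negative controls there, 1403. Sc5d was at least 1.92-fold higher in 1 probe set, and at least 1.08-fold lower in the other. The cholesterol list stood apart under only 3 of 12 alternatives, and its median was -0.03 with scaling to the spikes. Of the heat shock genes, 17 of 21 measured members had a ratio above 0, with a median of 0.21 at percentile 88.4. The oxidative stress gene Hmox1 was 2.82-fold higher, while Hspb8 and Cct3 had 0.75 and 0.86 on the log2 scale, against at least 1.14-fold lower and a log2 ratio of -1.27 in other probe sets. Among 22 hypoxia and glycolysis genes, 6 were at least 2-fold higher and 1 lower, with a median of 0.10 at percentile 75.4. It was -0.01 after quantile normalization and -0.02 after loess. The glucose transporter gene Slc2a1 was at least 3.19-fold higher and the hexokinase gene Hk2 4.11-fold in 1 of its probe sets, while another was at least 1.06-fold lower.

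**Figure D2:**
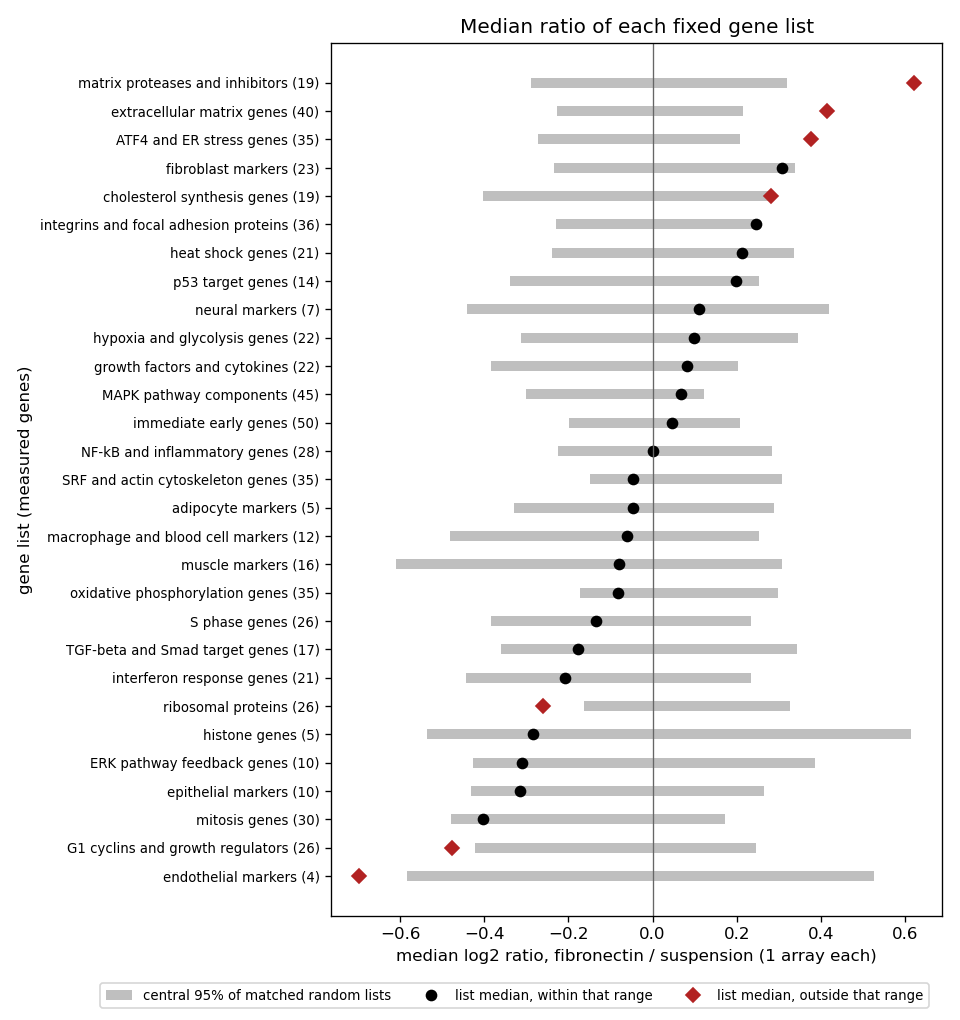
Median log2 ratio, fibronectin over suspension, of 29 of the 30 gene lists (points; x axis in log2 units, measured genes in parentheses on the y axis) over the central 95% of medians of 10000 random lists matched on signal (grey bars), from 1 array per group. Red diamonds mark the 7 lists outside that range, 4 of them above it, led by matrix proteases and inhibitors at 0.62, and 3 below it, among them ribosomal proteins at -0.26.

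Integrin and focal adhesion genes had a median of 0.25 at percentile 97.16, just inside the range of random lists, and stood apart under 6 of 12 alternatives, with percentiles from 73.1 to 99.97 and a median of -0.10 with scaling to the spikes. It had 12 of 36 measured members at least 1.5-fold higher and 3 lower. Beside Itga5, the beta subunit gene Itgb1 was 2.22-fold higher (log2 ratio of its second probe set 0.31) and the hyaluronan receptor gene Cd44 was 2.85-fold higher, and at least 1.08-fold lower in its second probe set. Itga8 was at least 2.53-fold lower. Of 35 genes of the actin cytoskeleton and its regulator SRF, 0 were at least 2-fold higher and 1 was at least 2-fold lower. Actb was 2.39-fold lower in the brighter of its 2 gene probe sets and had a log2 ratio of -0.59 in the other. The 3 brighter control probe sets of beta-actin gave -0.24, 0.35 and 0.33, so its direction was not settled. Tmsb10 had a log2 ratio of -0.89 and the membrane linker gene Rdx 0.91. The list median was -0.05 at percentile 15.3. TGF-beta and Smad target genes had a median of -0.18 at percentile 17.6, with Ccn2 and Id1 the lowest of 17 and Bhlhe40 (2.08-fold) the highest. Under median scaling the medians of the actin and TGF-beta lists were above 0, at 0.16 and 0.03.

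Lists of growth control and translation lay lower on fibronectin. Of 26 measured G1 cyclins and growth regulators, 11 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median of -0.48 at percentile 1.06. Among the members with the largest ratios were regulators that restrain the cycle. The retinoblastoma relatives Rbl1 and Rbl2 were at least 2.07-fold and 1.87-fold lower, and Tgfb2 at least 2.11-fold. The suspension signals of Rbl1, Rbl2 and Tgfb2, 1016, 914 and 1034, lay below the 95th percentile of negative controls there, 1403. Their fibronectin signals lay below the floor, so both arrays were near background for them. The kinase inhibitors Cdkn2a and Cdkn2c were 1.75-fold and 1.74-fold lower, while Tgfb1 was 2.31-fold higher. The list no longer stood apart with a floor at the 60th percentile of signals or at the level of the negative controls. Ribosomal protein genes were lower in 23 of 26 measured members, by small amounts, with a median of -0.26 at percentile 0.14. Under median scaling 16 were lower and 10 higher, with a median of -0.06. Rps10, with a signal of 159103 in suspension and 101270 on fibronectin, was 1.57-fold lower and Rpsa 1.54-fold lower. Rps29 and Rpl38 were 2.79-fold and 2.55-fold lower, Rps13 at least 1.77-fold, and Rpl22 had a log2 ratio of 0.59 in 1 probe set and -1.18 in the other. This list did not stand apart after quantile normalization or loess.

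Mitosis genes had a median of -0.40 at percentile 7.41, with 11 of 30 at least 1.5-fold lower and 1 higher. The kinesin gene Kif4 was 3.40-fold lower, the centromeric histone gene Cenpa at least 3.01-fold and the checkpoint gene Mad2l1 at least 2.58-fold. Their suspension signals were 1682, 1474 and 1263, against a 95th percentile of negative controls there of 1403. None of them kept a 2-fold difference under every alternative. S phase genes had a median of -0.13 at percentile 48.8. The licensing factor Cdc6 was 2.60-fold lower and Rpa1 2.04-fold lower, and Cdt1 was 2.16-fold higher with 0.14 on the log2 scale in its second probe set. Oxidative phosphorylation genes had a median of -0.08 at percentile 12.7, and Cox6b1, Atp5e and Ndufs1 were 1.99-fold, 1.86-fold and 1.81-fold lower. Under median scaling the S phase and oxidative phosphorylation medians were above 0, at 0.07 and 0.13. The 5 measured histone genes had a median of -0.28 at percentile 18.5, with H1f2, H2az1 and H2ax at -0.71, -0.35 and -0.28. Targets of p53 had a median of 0.20 at percentile 93.8, with Plk2 and Gtse1 at 0.61 and 0.60 and the cell cycle inhibitor Cdkn1a at -0.67.

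Signalling by cytokines gave no common direction. NF-kB and inflammatory genes had a median of 0.00 at percentile 46.6, with 3 of 28 at least 2-fold higher and 4 lower. The prostaglandin synthase gene Ptgs2 was 3.55-fold higher, Tnfaip2 at least 3.19-fold and the growth factor gene Csf3 at least 2.61-fold. Their signals on fibronectin, 1818, 1563 and 1276, lay below the 95th percentile of negative controls there, 1873. Interferon response genes had a median of -0.21 at percentile 39.0, with Ifit3 2.13-fold lower, Irf7 1.70-fold lower and the GTPase gene Igtp at least 2.05-fold higher. Growth factor and cytokine genes had a median of 0.08 at percentile 87.2, with Vegfa and the endothelial ligand Angpt1 (2.41-fold) higher and Ccn2 lower.

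Markers of fibroblasts had a median of 0.31 at percentile 96.1, with 7 of 23 at least 1.5-fold higher and 2 lower. The growth factor receptor gene Pdgfrb was 3.35-fold higher and Cd34 at least 3.95-fold, with at least 3.03-fold in its second probe set. Many measured markers of other cell types had 1 array below the floor, 7 of 10 for epithelium and 7 of 16 for muscle. The 4 measured endothelial markers were all lower, with Eng 2.13-fold lower, Emcn at least 1.78-fold, Pecam1 at least 1.48-fold and Tek at least 1.07-fold, and a median of -0.70 at percentile 0.38. The array on fibronectin lay below the floor for 3 of these 4 genes, and the list did not stand apart with a floor at the 20th percentile, with no floor, with an offset or with scaling to the spikes. Epithelial markers had a median of -0.32 at percentile 11.5, with Cldn4 at least 2.88-fold, Muc1 at least 2.13-fold and Cdh1 1.94-fold lower. Muscle markers went both ways around a median of -0.08 at percentile 71.4, with Chrng at least 2.78-fold and Ckm 2.50-fold lower and Tnnc1 at least 2.46-fold higher. Macrophage and blood cell markers had a median of -0.06 at percentile 58.5, with Fcgr3 at least 3.59-fold and the globin gene Hba-a1 2.11-fold lower and Gata1 at least 1.58-fold higher. The muscle and blood cell medians were 0.13 and 0.10 under median scaling. Adipocyte markers had a median of -0.05 at percentile 43.1, with Cebpa and Lep at -0.46 and 0.18, Lipe at least 1.25-fold lower, and Lep at least 1.32-fold lower in its second probe set. Neural markers had a median of 0.11 at percentile 69.2, with Gfap and Mapt at least 2.70-fold and 2.31-fold lower and Mbp at least 1.34-fold higher.

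The 2 arrays differed in measures of RNA, hybridisation and background as well. All 9 hybridisation spikes had higher signals on fibronectin, with log2 ratios from 0.02 to 0.94 and a median of 0.47. The signal of the 3′ probe set over that of the 5′ probe set was 1.79 for beta-actin in suspension and 1.19 on fibronectin, and 1.47 and 0.84 for Gapdh. It was 4.90 and 3.62 for 18S rRNA and 2.43 and 2.35 for pyruvate carboxylase. For the transferrin receptor it was 2.84 and 4.41, but its 5′ signals, 456 and 153, lay below the floor. The 34 negative control probe sets had a median signal of 459 in suspension and 292 on fibronectin, a 95th percentile of 1403 and 1873 and a maximum of 1452 and 2527, and 18 of them reached the floor in at least 1 array. Of these, 3 were at least 2-fold lower on fibronectin and 0 at least 2-fold higher. The upper limits on fibronectin came from antisense probe sets, with a maximum of 2527, against 658 for Bacillus and 646 for yeast genes. In suspension these maxima were 1452, 1136 and 1141. For 1146 genes with more than 1 measured probe set, the log2 ratios of the brightest 2 probe sets correlated with r = 0.19, and the spread between them corresponded to an SD of 0.69 for 1 ratio. The SD was 0.59 for genes in the highest tertile of signal. Of 174 genes whose first probe set gave at least a 2-fold difference, the second had the same sign in 114 and passed 2-fold the same way in 25. Among the genes taken by the naming rule with at least a 2-fold difference, 13 of 50 higher genes and 2 of 38 lower genes kept it under every alternative that measured them. With the floor from the negative controls alone, 22 and 7 kept it. Of those above the main floor in both arrays, 19 of 34 higher and 16 of 20 lower genes had their dimmer signal below that array's 95th percentile of negative controls, so these folds rest on signals near background. The higher ones included Angpt1, Bhlhe40, Cd44, Cyp1b1, Dnajb9, Eln, Fdft1, Hk2, Lamc1, Mknk1, Mmp13, Mmp9, Nid2, Ptgs2, Tcirg1, Tgfb1 and Tmem41b. The lower ones were Canx, Ccn2, Cdc6, Ckm, Etv4, Hba-a1, Ifit3, Kif4, Krt17, Map2k4, Mapk9, Per3, Rpa1, Rpl38, Rps29 and Snrp1c-ps2. Higher genes that kept 2-fold under every alternative were Col5a2, Col6a3, Cyp1b1, Hmox1, Itga5, Pdgfrb, Pdia3, Pdia6, Slc20a1, Sqle, Tcirg1, Timp2 and Tmem41b. Lower genes that kept it were Id1 and Snrp1c-ps2, the latter measured under 11 of 12 alternatives.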

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

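The floor at the level of the negative controls and the scaling to hybridisation spikes were chosen after seeing the data. Signal over background limits these results, since 18 of 34 negative control probe sets reached the main floor. The counts of 2-fold higher and lower genes, 370 and 592, were 817 and 1179 with a floor at the 20th percentile, 155 and 158 at the 60th, 931 and 1542 with no floor, 226 and 392 with an offset, 88 and 120 at 3-fold, 96 and 47 with the negative control floor, and 135 and 1396 with scaling to the spikes. By construction a higher floor counts fewer genes of low signal. Median scaling gave 596 higher genes, a median of 0.25 for immediate early genes and 0.18 for MAPK components, as it shifts every ratio up. Scaling to the spikes shifts every ratio down, with medians of -0.42 for immediate early genes and -0.35 for MAPK components, and of the lists that stood apart the medians of the extracellular matrix (-0.063), ATF4 (-0.091) and cholesterol (-0.034) lists changed sign. The MAPK median was -0.15 with the floor at the 20th percentile, -0.045 at the 60th and -0.20 with no floor; the cause was not tested. The number of the 28 other lists that stood apart, 7, was 4 at the 60th percentile and 4 with the negative control floor, and 6 or 7 otherwise. With plain probe sets alone the ratios of Etv4 and Lamc1 had the opposite sign, 0.41 or more and -0.31, because another probe set was read, and with scaling to the spikes 1 gene not named here went to -1.22. The other lists gave 330 values, of which 258 lay within the spread of random lists around the main median and 69 beyond it, not counting the 3 sign changes above of lists that stood apart. In all, 33 had a sign other than that of the main median. The 132 genes taken by the naming rule gave 1522 values, 1384 within the probe set spread of 0.69 and 135 beyond it. Marker lists with under 3 measured genes at the higher floors gave no value there. No paired analysis was possible because each group had 1 array.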

Other observations

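The tests of low signals, of all kinds of scaling and of the instrument settings were chosen or narrowed after the results they bear on had been seen; the tests of other probe sets, of gene length and of the symbol classes were written down first.

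Several of the genes highest on fibronectin encode membrane or secreted proteins, among them Slc20a1, Notch1, Tmem41b and Efna1. A hypothesis drawn from these genes was that transcripts of this kind were higher as a class, beyond the lists already described. Its test was written down before it was run. The genes that prompted it were not left out, however, and every value comes from the same 2 arrays. A class of 402 measured genes was formed from symbol prefixes of membrane and secreted protein families, leaving out the adhesion, matrix, protease, endoplasmic reticulum and fibroblast lists. Its median log2 ratio was 0.06, small in size but at percentile 99.99 of matched random lists, and 0.26, 0.17 and 0.18 under median scaling, quantile normalization and loess. At 2-fold it held 45 higher and 40 lower members. In 56 probe sets of 53 class genes that were not used for that median, it was 0.34 at percentile 99.89. A class of 480 genes of nuclear and cytosolic families had a median of -0.16 at percentile 0.10, with 13 members at least 2-fold higher and 45 lower, so the ratio was not raised in every class. The nuclear and cytosolic median was 0.04 under median scaling, at percentile 0.15. These values fit a difference between transcripts translated at the endoplasmic reticulum and others in these 2 arrays, but give it no independent support. Such a difference may come from the cells or from how RNA was released from attached and unattached cells. No biological explanation was tested.

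The higher ratios of the extracellular matrix, matrix protease and ATF4 lists were weighed against 5 technical explanations. Noise of single probe sets is argued against by 31 other measured probe sets of 25 of these genes, whose median of 0.55 lay at percentile 99.75. Scaling that depends on intensity is argued against because the lowest percentile of the 3 lists under quantile normalization and loess was 97.84, for the ATF4 list, close to the bound of the central 95%. A single factor for all genes moves a list's place among random lists only through the floor and the filter. Its percentile therefore says little there, but the factor sets whether a median lies above 0. With scaling to the hybridisation spikes the lowest of the 3 medians was -0.091, within the standard error of the spikes, 0.11, so global scaling stays open for the sign of these ratios. Gene length as the whole cause is argued against, since the 94 genes joined had a median of 0.43 at percentile 100 of lists matched on signal and genomic length, although transcript length was not measured. The differences in 3′ to 5′ signal between the arrays were not weighed, as the position of probe sets along the transcript was not checked. The chip lot, operator, fluidics module and scan day, 4 settings that differ between the arrays, cannot be told apart from the plating on fibronectin, and contact with fibronectin itself and the time out of suspension stay open and untested.

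That more genes were 2-fold lower than higher on fibronectin may be a matter of scaling. Noise of low signals on the suspension array stays open. In the highest tertile of signal 46 genes were lower against 88 higher, and 3 negative control probe sets were 2-fold lower and 0 higher, as such noise predicts. Yet the excess was as large in the middle tertile, 284 lower against 144 higher, as in the lowest, 262 against 138, and 311 genes were lower against 224 higher with both arrays above the floor. The choice of scaling bears on it, since up to 59.5% of the 2-fold genes were higher under the other 4 planned scalings, and 8.82% with scaling to the spikes. The signals in suspension of Clps, Prl and Krt17, all among the 10 lowest genes, were 2740, 2501 and 2444, above the highest negative control there, 1452. Choosing the lowest ratios against the floor required such signals, so they cannot tell noise from a difference, and these ratios stay open. A true fall of many transcripts of low level was not tested.

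The control probe set for the mouse B1 repeat, a short interspersed element found in many transcripts, had a signal of 76086 in suspension and 41511 on fibronectin. Of the 2 probe sets for the B2 repeat, one had 5336 and 2879, and the other 125067 and 125323.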
